A study of Homo sapiens with 13 samples.

How the data were processed

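The series held 13 RNA sequencing libraries of naive CD4 T cells of 2 donors in 4 conditions. Per the labels, cells were isolated by negative selection from buffy coats and cultured for 5 days on plate-bound anti-CD3 with or without IL-23 plus IL-1β and with or without anti-CD28. Total RNA was then extracted for library preparation. Per the submitters' processing notes, the tools were Trimmomatic and Cufflinks 2.2.1, and the genome build was GRCh38. The aligner and the annotation are not given in the sources used here, nor is whether the libraries kept the strand, so reads of overlapping or antisense genes cannot be told apart.

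The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the total of mapped fragments) with 65535 lines of transcripts and 1 column per library. FPKM is a normalized unit, so no count test was used, and the sequencing depth of each library is unknown. The lines were sorted by transcript identifier and held 99.8% of the GENCODE 29 transcripts with an identifier up to the last listed one, and 0 of the 150088 with a higher one. They held 38273 of 83101 protein-coding transcripts of GENCODE 29 (46.1%), and 1731 of 19688 protein-coding genes had no coding transcript listed. Of the lines, 109 had a spreadsheet date in place of a gene name; 102 were named through their transcript identifier and 7 were left out. FPKM of listed transcripts were summed per gene symbol. Of the lines, 86.0% had an identifier in GENCODE 29, and 84.9% of those used carried the same symbol there. Among genes named below, CCL3, CCL4, CCL5, CST7, NOP16 and UHRF1 had no listed transcript in GENCODE 29. How many of their transcripts are missing is unknown, so their values are uncertain. Genes of the Y chromosome, XIST and TSIX entered no step. Where a gene's main isoform is not listed, its value is too low, and a shift between isoforms can look like a change of the gene.

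Genes with at least 1 FPKM in at least 2 of the 13 libraries were tested: 12373, of which 10622 are protein-coding in GENCODE 29 and 2856 of these had every coding transcript listed. Values were taken as log2(FPKM + 1). Repeat libraries of 1 donor in 1 condition were averaged to 8 values. All 4 conditions entered 1 limma fit (limma 3.58.1 in R 4.3.3, with a mean-variance trend and 3 residual and 3.76 prior degrees of freedom) with the donor as a term. The labels give the donor of each library and thereby the pairing; across genes, the difference between the donors correlated between conditions at r = -0.22 to 0.29. The contrasts were Th17 against Th0, Th17CD28 against Th17, Th0CD28 against Th0, Th17CD28 against Th0CD28, and the interaction, which is the anti-CD28 effect with the cytokines minus that without them. P-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. Means are of 2 donor means, and each SD is between them. Gene lists were tested with camera from limma at a preset correlation of 0.01 for the 23 lists with at least 5 tested members, adjusted over the lists of a contrast, and again with the correlation estimated from the residuals. With an estimated correlation camera takes its degrees of freedom from the residuals, 3 in the main fit, so small p-values are hard to reach whatever the correlation. A list call lost there does not show that the correlation was the cause. Coordinates are those of GENCODE 29 on GRCh38. Figures were drawn with matplotlib 3.10.9.

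The groups, the design, the gene lists and the rule for named genes were set before the data were examined. The rule took, per pairwise comparison, the 6 genes with the largest positive and the 6 with the largest negative log2 difference among those called, with the same sign in both donors and a mean of at least 5 FPKM in the higher group, and 5 and 5 for the interaction. It left out genes without a symbol, small RNAs, pseudogenes, antigen receptor segments and HLA genes. It added up to 3 called members per list and a set of 35 tested genes whose call or lack of a call is described. From this pool a part is named in the text, and some genes are not reported here.

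The steps were tested on simulated data for Th17CD28 against Th17 with 11953 genes, of which 50 were changed at each of 4 sizes. Of 50 genes changed by a log2 of 1, 4 were recovered (8.00%), of those changed by 2, 44 (88.0%), and of those changed by 3 or 4, all 50 (100.0%), with 8 false calls. The changed list passed camera and 0 of 22 random lists did. The simulated genes varied independently of each other, whereas the real cell cycle list had an estimated correlation of 0.76. This check therefore does not cover false list calls in the real data. In this simulated comparison, where few genes changed, a log2 change of 1 was thus mostly missed. The simulation also added the spread of repeats to that of the donor means, which already holds it. The share missed does not carry over to every comparison. In Th0CD28 against Th0, 3640 of the 4837 genes called had at least a 2-fold change, so smaller changes were called too.

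Other settings, chosen before the data were seen, were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, upper-quartile scaling, quantile normalization, no donor term, 13 libraries as separate observations, no variance trend, a minimum fold of 2 and each library left out in turn. Added after seeing the data were transcripts as features, only genes with every coding transcript listed, mitochondrial transcripts left out, and the camera correlation estimated on 13 libraries.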

Results

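Naive CD4 T cells were taken by negative selection from buffy coats, the white cell layer of donated blood, of 2 donors and cultured for 5 days under 4 conditions. All cells were stimulated with plate-bound anti-CD3, an antibody that triggers the T cell receptor complex. Th0 cells had anti-CD3 alone, and Th0CD28 cells also had anti-CD28, an antibody to the costimulatory receptor CD28. Th17 cells had anti-CD3 with IL-23 and IL-1β, cytokines that act on Th17 cells, and Th17CD28 cells had these cytokines together with anti-CD28. The series asks how the Th17 gene programme looks when CD28 costimulation is present. Total RNA was sequenced in 13 libraries: 2 of Th0, 4 of Th0CD28, 3 of Th17 and 4 of Th17CD28. Each condition held both donors, and 5 pairs of libraries were repeats of 1 donor in 1 condition. The labels do not say whether the repeats were separate cultures, so their spread may be technical. They were averaged, and n is 2 donors throughout.

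The libraries had summed values of 394756 to 510358 FPKM and 10474 to 11081 genes of at least 1 FPKM. The number of reads behind these values is unknown, because FPKM does not keep it. Mitochondrial transcripts took 14.0% to 25.5% of the summed FPKM, and the 10 most abundant genes took 15.0% to 24.0%. Repeat libraries correlated across genes at r = 0.961 to 0.976 on the log2 scale; genes are not independent replicates. The table listed 46.1% of the protein-coding transcripts of GENCODE 29, and the median tested coding gene had 50% of its coding transcripts listed. A gene's FPKM here is therefore a sum over listed transcripts, and unlisted isoforms are not analysed here. Differences below are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

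Markers of other blood cells were low in part. Among monocyte genes, S100A8 and S100A9 reached 11.7 and 16.0 FPKM in 1 of the 2 Th0 libraries, against means of 0.214 and 0.11 FPKM or less in the other conditions. FCER1G, of the same list, reached 27.7 FPKM in 1 Th0 library and averaged 11.5 in Th17, against 3.95 in Th0CD28 and 3.98 in Th17CD28. TRDC, of the gamma-delta T cell list, averaged 5.65 to 12.6 FPKM. The B cell gene MS4A1 had means of at most 0.0196 FPKM. CD8B averaged 2.26 FPKM in Th0 and 2.53 in Th17, against 25.9 in Th0CD28 and 26.1 in Th17CD28. CD8A, its partner in the CD8 receptor, had means of at most 2.75 FPKM and reached 3.65 in 1 library. CD79A, a B cell receptor component, averaged 1.74 and 0.868 FPKM without anti-CD28 against 10.6 and 9.94 with it. CD68, a lysosomal protein abundant in macrophages, averaged 0.0466 and 0.218 against 2.98 and 9.47.

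The comparison of Th17 with Th0 gives the effect of IL-23 and IL-1β without anti-CD28. IL17F, a cytokine of Th17 cells encoded on chromosome 6 at 52236681 to 52244537 (GRCh38), averaged 752 ± 858 FPKM in Th17 and 0.0657 ± 0.0929 FPKM in Th0 (SD, n = 2 donors), a log2 difference of 8.71 ± 0.98 (SE; limma adjusted p = 0.00971). IL26, another Th17 cytokine, rose by 4.36 ± 0.38 (adjusted p = 0.00697). IL17A (chromosome 6, 52186375 to 52190638) rose by 3.32 ± 0.48 (adjusted p = 0.018). The receptor gene IL23R rose by 2.07 ± 0.42, from 0.0774 to 4.07 FPKM, whereas IL22 differed by 0.58 ± 0.30 and did not pass (adjusted p = 0.284). Of 21 tested members of the Th17 list, 9 rose and 12 did not pass, and 13 rose when adjusted over the list alone (camera adjusted p = 6.18e-08; adjusted p = 0.111 with an estimated correlation).

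Genes of other effector programmes rose as well. In the Th1 list 7 of 18 members rose, 15 when adjusted over the list alone (camera adjusted p = 1.48e-08; adjusted p = 0.0959 with an estimated correlation). They included TBX21, the T-bet transcription factor of Th1 cells, by 2.95 ± 0.31 and its target IFNG by 2.60 ± 0.47. The chemokine genes CCL4 (4.78 ± 0.40) and CCL3 (4.65 ± 0.44) were also among them, but both have near-identical copies in the genome, so their values are uncertain. Of 11 cytotoxic granule genes 7 rose, 9 when adjusted over the list alone (camera adjusted p = 1.4e-06; adjusted p = 0.177 with an estimated correlation). GZMB, which encodes the protease granzyme B, rose by 4.52 ± 0.56, from 17.2 to 313 FPKM, NKG7 by 4.62 ± 0.43 and CST7 by 3.87 ± 0.39. KLRC1, a marker of NK cells, rose by 1.09 ± 0.22, from 0.154 to 1.48 FPKM, and BLK of the B cell list and TRGC2 of the gamma-delta T cell list rose only when adjusted over their lists alone. In the list of IL-1 and IL-23 pathway components 5 of 22 members rose, 9 when adjusted over the list alone, including the signalling inhibitor SOCS3 at 2.31 ± 0.30 (camera adjusted p = 0.00023; adjusted p = 0.111 with an estimated correlation). The list call was lost among genes with every coding transcript listed. IL2RA, the high-affinity chain of the IL-2 receptor, rose by 3.08 ± 0.26 and the homing receptor CXCR6 by 2.88 ± 0.27.

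Proliferation and metabolism genes moved in the same direction. Of 38 cell cycle genes 29 rose, 35 when adjusted over the list alone (camera adjusted p = 1.05e-24; adjusted p = 0.22 with an estimated correlation), among them TYMS (4.13 ± 0.42), CDC20 (4.09 ± 0.49), RRM2 (4.01 ± 0.39) and the proliferation marker MKI67 (3.17 ± 0.40). Of 24 glycolysis genes 8 rose, 12 when adjusted over the list alone, with LDHA at 2.47 ± 0.36, GAPDH at 2.15 ± 0.31 and ENO1 at 2.12 ± 0.27 (camera adjusted p = 3.84e-06; adjusted p = 0.22 with an estimated correlation). In the amino acid list 5 of 21 members rose, 12 when adjusted over the list alone, including the amino acid transporter SLC7A5 at 3.77 ± 0.34 (camera adjusted p = 4.06e-06; adjusted p = 0.265 with an estimated correlation). Of 38 oxidative phosphorylation genes 4 rose, 19 when adjusted over the list alone, including the cytochrome c gene CYCS at 1.82 ± 0.37 (camera adjusted p = 2.46e-08; adjusted p = 0.298 with an estimated correlation). The transferrin receptor TFRC rose by 3.35 ± 0.35 and the desaturase SCD by 2.29 ± 0.30. In the naive and resting T cell list 2 of 16 members fell and 14 did not pass, with 4 falling when adjusted over the list alone (camera adjusted p = 3.84e-06; adjusted p = 0.111 with an estimated correlation): IL7R, the IL-7 receptor, fell by 1.73 ± 0.33 and PIK3IP1, an inhibitor of PI3 kinase, fell by 1.28 ± 0.24. The interferon response list did not pass (median 0.28; camera adjusted p = 0.929). Without Th17 replicate 3 it passed as lower, with a median of -0.12. Outside the lists, LGALS1 (galectin-1) rose by 5.70 ± 0.78, TNFRSF8 (CD30) by 4.70 ± 0.44 and the tubulin gene TUBB3 by 4.67 ± 0.47, while the tropomyosin gene TPM2 fell by 2.12 ± 0.21 and the keratin gene KRT72 fell by 1.81 ± 0.33.

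In all, limma with the donor as a term called 612 of 12373 genes, 548 higher and 64 lower in Th17 (89.5% higher), and all 612 had the same sign in both donors. A call from 2 donors nearly requires the same sign, which 66.8% of all tested genes had. The count was 294 with no replicate block, which lost CYCS, GZMB, IL23R, IL2RA, KLRC1, KRT72, PIK3IP1 and SOCS3, and 22 with no filter on low values, which lost all 33 genes described above as changed. Without Th0 replicate 1 it was 368 (CYCS, IFNG, IL23R, IL7R, KLRC1, KRT72 and PIK3IP1 missed the threshold), without Th0 replicate 2 it was 336 (IFNG, IL23R, IL7R, KLRC1 and PIK3IP1) and without Th17 replicate 3 it was 392 (CYCS, IFNG, IL17A, IL7R, KRT72, PIK3IP1 and SOCS3). Without Th17CD28 replicate 1, CYCS, IL23R, IL7R, KLRC1 and PIK3IP1 missed it, and without Th17CD28 replicate 4, CYCS and KLRC1 did. The median difference of all genes moved from 0.05 to -0.06 with upper-quartile scaling and to -0.11 with quantile normalization; IL23R missed the threshold under the latter and, with a filter at 5 FPKM, as well. KLRC1 missed it under both scalings and with a pseudocount of 0.1.

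**Figure D1:**
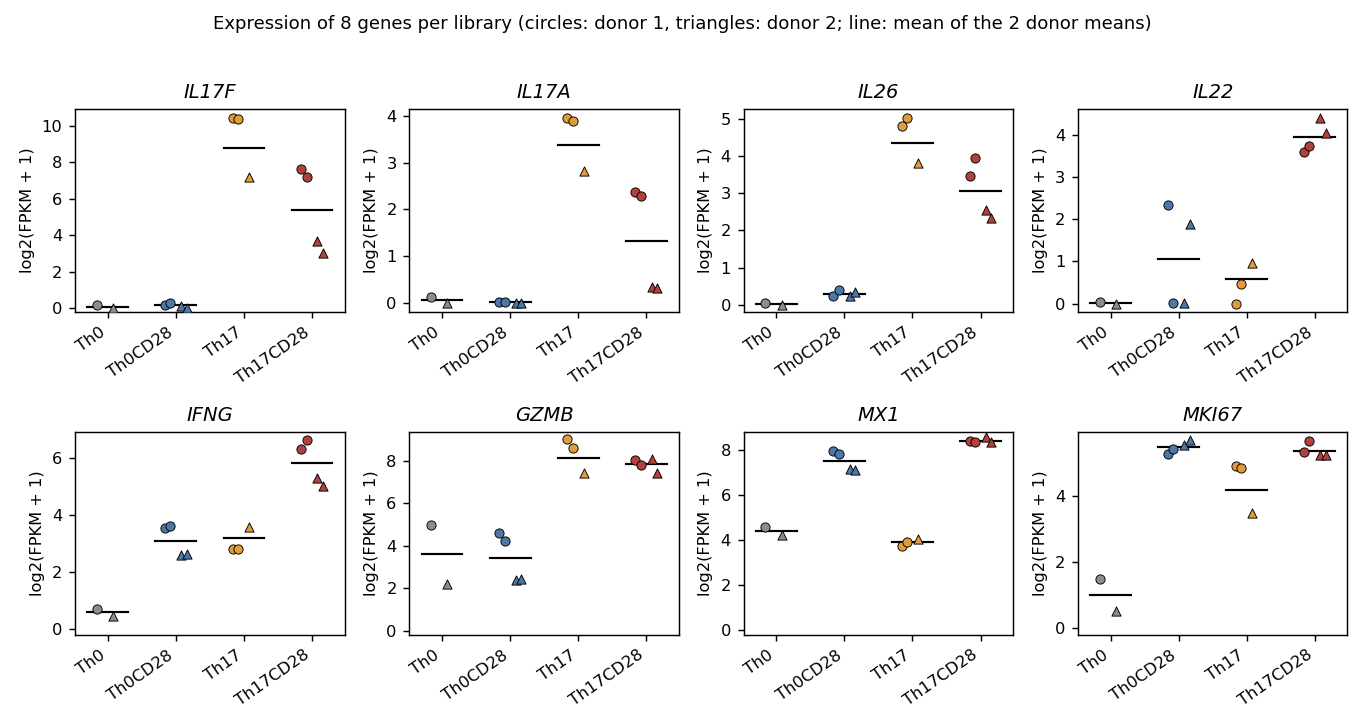
Expression of 8 genes as log2(FPKM + 1) on the vertical axis in each of the 13 libraries, grouped by condition on the horizontal axis; circles are donor 1, triangles donor 2 and the line is the mean of the 2 donor means. IL17F averaged 752 FPKM in Th17 and 91.5 FPKM in Th17CD28, IL22 averaged 0.564 and 14.7 FPKM, and MX1 averaged 14.2 and 342 FPKM.

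The comparison of Th17CD28 with Th17 gives the effect of anti-CD28 beside the cytokines, the question in the title of the series. The Th17 genes went both ways. IL22 (chromosome 12, 68248242 to 68253604), a cytokine that acts on epithelial cells, rose by 3.35 ± 0.30 (SE, n = 2 donors; limma adjusted p = 0.00499), from 0.564 ± 0.537 to 14.7 ± 4.26 FPKM (SD). IL21 rose by 1.78 ± 0.25 (adjusted p = 0.0127). IL17A fell by 2.05 ± 0.48 (adjusted p = 0.0488), and KLRB1, the CD161 receptor found on Th17 cells, fell by 1.85 ± 0.29. IL17F averaged 752 FPKM in Th17 and 91.5 ± 116 in Th17CD28, a difference of -3.41 ± 0.98 that did not pass (adjusted p = 0.0765), and IL26 differed by -1.29 ± 0.38 (adjusted p = 0.079). Of 21 tested members of the Th17 list 5 rose, 5 fell and 11 did not pass, against 6 and 8 adjusted over the list alone (camera adjusted p = 0.0768).

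Among other cytokine genes, IFNG rose by 2.61 ± 0.47, from 8.43 to 60.9 FPKM, the Th2 cytokine IL13 by 3.97 ± 0.74, IL2 by 2.15 ± 0.37 and LIF by 4.63 ± 0.34, while IL10 fell by 1.30 ± 0.22. Of the 18 Th1 list members 6 rose and 3 fell, 7 and 5 when adjusted over the list alone (camera adjusted p = 0.532). The chemokine CCL5 rose by 2.57 ± 0.36 and CCL4, uncertain as above, fell by 3.74 ± 0.40. In the regulatory T cell list 5 of 16 members rose and 1 fell, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00783; adjusted p = 0.418 with an estimated correlation), with FOXP3, the transcription factor of these cells, at 2.02 ± 0.41 and IL2RA at 1.74 ± 0.26. GZMB differed by -0.29 ± 0.56 (adjusted p = 0.773).

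Interferon response genes rose together. Of 27 tested members 23 rose and 4 did not pass, and 27 rose when adjusted over the list alone (camera adjusted p = 2.27e-20; adjusted p = 0.29 with an estimated correlation). MX1 (chromosome 21, 41420304 to 41459214), an antiviral GTPase, rose by 4.49 ± 0.29 (adjusted p = 0.00292), from 14.2 ± 1.59 to 342 ± 18.1 FPKM (SD, n = 2 donors), IFI44L by 4.30 ± 0.49 and CMPK2 by 4.27 ± 0.42.

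Several metabolic lists also rose. Of 24 glycolysis genes 13 rose, 18 when adjusted over the list alone (camera adjusted p = 3.83e-09; adjusted p = 0.29 with an estimated correlation), led by PFKFB4 (chromosome 3, 48517684 to 48562015), a regulator of glycolytic flux, at 4.98 ± 0.30, with ALDOC at 3.02 ± 0.24 and hexokinase HK2 at 1.70 ± 0.26. Of 16 hypoxia response genes 11 rose, 13 when adjusted over the list alone, including VEGFA at 3.42 ± 0.35 and BNIP3 at 3.01 ± 0.43 (camera adjusted p = 3.19e-09; adjusted p = 0.29 with an estimated correlation). Of 21 genes of the amino acid response and serine synthesis 16 rose, 18 when adjusted over the list alone (camera adjusted p = 1.11e-11; adjusted p = 0.29 with an estimated correlation), such as DDIT4 at 3.97 ± 0.26, TRIB3 at 3.08 ± 0.32 and PHGDH, the first enzyme of serine synthesis, at 3.02 ± 0.35. Of 28 cholesterol and fatty acid genes 7 rose, 10 when adjusted over the list alone, led by the desaturases FADS2 at 4.85 ± 0.26 and SCD at 3.62 ± 0.30 (camera adjusted p = 8.3e-07; adjusted p = 0.29 with an estimated correlation). HILPDA, a lipid droplet protein, rose by 4.68 ± 0.42 and ASS1, an enzyme of arginine synthesis, by 4.53 ± 0.40. In the oxidative phosphorylation list 0 of 38 members were called, 0 when adjusted over the list alone, and the list did not pass (median 0.15; camera adjusted p = 0.49). Of 38 cell cycle genes 2 rose and 36 did not pass (camera adjusted p = 8.99e-07; adjusted p = 0.465 with an estimated correlation), with 0 when adjusted over the list alone. MKI67 averaged 19.4 and 41.2 FPKM and did not pass (adjusted p = 0.111).

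In the naive and resting list 4 of 16 members fell and 12 did not pass, again 4 when adjusted over the list alone (camera adjusted p = 8.81e-06; adjusted p = 0.29 with an estimated correlation). KLF2 (chromosome 19, 16324817 to 16327874), a transcription factor of resting T cells, fell by 4.53 ± 0.29, from 132 to 4.88 FPKM, and PIK3IP1 fell by 2.35 ± 0.24. RASGRP2, an activator of Rap1, fell by 3.95 ± 0.44, the transcription factor gene MSC fell by 3.85 ± 0.38, FUT7, which makes selectin ligands, fell by 3.84 ± 0.36, and the pseudokinase TRIB2 fell by 3.49 ± 0.23. Other lists moved in part. In the stress list 4 of 12 members rose, 6 when adjusted over the list alone, with the transcription factors ATF3 at 3.74 ± 0.36 and JUN at 2.66 ± 0.28 (camera adjusted p = 0.0319; adjusted p = 0.352 with an estimated correlation). The list call was lost with a filter at 5 FPKM. Of 22 IL-1 and IL-23 pathway components 5 rose, 8 when adjusted over the list alone, with the IL-18 receptor IL18R1 at 2.34 ± 0.22 (camera adjusted p = 0.0319; adjusted p = 0.29 with an estimated correlation). This call was lost with a filter at 5 FPKM and without Th17CD28 replicate 1. Of 11 inhibitory receptors 3 rose and 1 fell, 7 and 1 when adjusted over the list alone, with HAVCR2 (TIM-3) at 2.26 ± 0.24 (camera adjusted p = 0.0319; adjusted p = 0.418 with an estimated correlation). With no filter on low values this call was lost. Of 16 chemokine and homing receptors 1 rose, CCR4 by 2.27 ± 0.47, and 3 fell, CXCR6 among them by -1.91 ± 0.27, against 1 and 4 when adjusted over the list alone (camera adjusted p = 0.0327; adjusted p = 0.452 with an estimated correlation). That list call was lost with a filter at 5 FPKM and without Th17 replicate 1, Th17 replicate 2 or Th17CD28 replicate 2, and the list median, -0.60, turned to 0.57 among genes with every coding transcript listed. Of 21 apoptosis regulators 4 rose, including PMAIP1 at 3.23 ± 0.29 and TNFSF10 (TRAIL) at 2.71 ± 0.30, against 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0657, past the threshold with no filter and without Th17 replicate 3 or Th17CD28 replicate 3). Of 24 MYC and ribosome biogenesis genes 2 fell, RRP9 by -1.06 ± 0.23 and SRM by -1.03 ± 0.24, against 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0848, past the threshold with either other scaling and without Th17 replicate 3). Among markers of other cells, CD8B rose by 2.94 ± 0.35, CD68 by 3.11 ± 0.41 and CD79A by 2.31 ± 0.40. Others fell: BLK by -1.68 ± 0.33, KLRK1 by -1.52 ± 0.24, CRTAM by -1.48 ± 0.22, FCER1G by -1.37 ± 0.24 and KLRC1 by -0.96 ± 0.22.

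In all, 1098 of 12373 genes were called by limma with the donor as a term, 737 higher and 361 lower in Th17CD28, and all 1098 had the same sign in both donors. Such agreement is nearly required for a call, and 72.2% of all tested genes had it. The share of higher genes was 67.1%, and 57.5% with upper-quartile scaling or 56.9% with quantile normalization, which moved the median of all genes from 0.08 to -0.03 and -0.02; FOXP3 and KLRC1 missed the threshold under both. The count was 713 with no replicate block, which lost CCR4, CD79A, FCER1G, FOXP3, HK2, IL13, IL17A, IL2, IL2RA, KLRC1, RRP9 and SRM, 111 with no filter on low values and 54 without Th17 replicate 3. Without that library, which was donor 2's only Th17 library, 34 of the 52 genes named as changed in this comparison missed the threshold: ATF3, BLK, BNIP3, CCL5, CCR4, CD68, CD79A, CD8B, CRTAM, CXCR6, FCER1G, FOXP3, HAVCR2, HK2, IFNG, IL10, IL13, IL17A, IL18R1, IL2, IL21, IL2RA, JUN, KLRB1, KLRK1, PHGDH, PIK3IP1, PMAIP1, RASGRP2, RRP9, SRM, TNFSF10, TRIB3 and VEGFA; KLRC1 was not tested there. With no filter 40 of the 52 missed it, among them IL22, IL17A, IFNG and KLRB1. The IL17A call was also lost with a pseudocount of 0.1, with a filter at 5 FPKM, and without Th0CD28 replicate 4, Th17 replicate 1, or Th17CD28 replicate 1 or replicate 4. Without Th17CD28 replicate 1, FOXP3, KLRC1, RRP9 and SRM were lost too, and SRM without Th17CD28 replicate 4. IL21 was lost with the filter at 5 FPKM and CCR4 and KLRC1 with the pseudocount of 0.1, with which IL17F passed. IL17F and IL26 passed without Th0 replicate 1 or Th0 replicate 2, and IL26 also with quantile normalization and without Th17CD28 replicate 2.

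**Figure D2:**
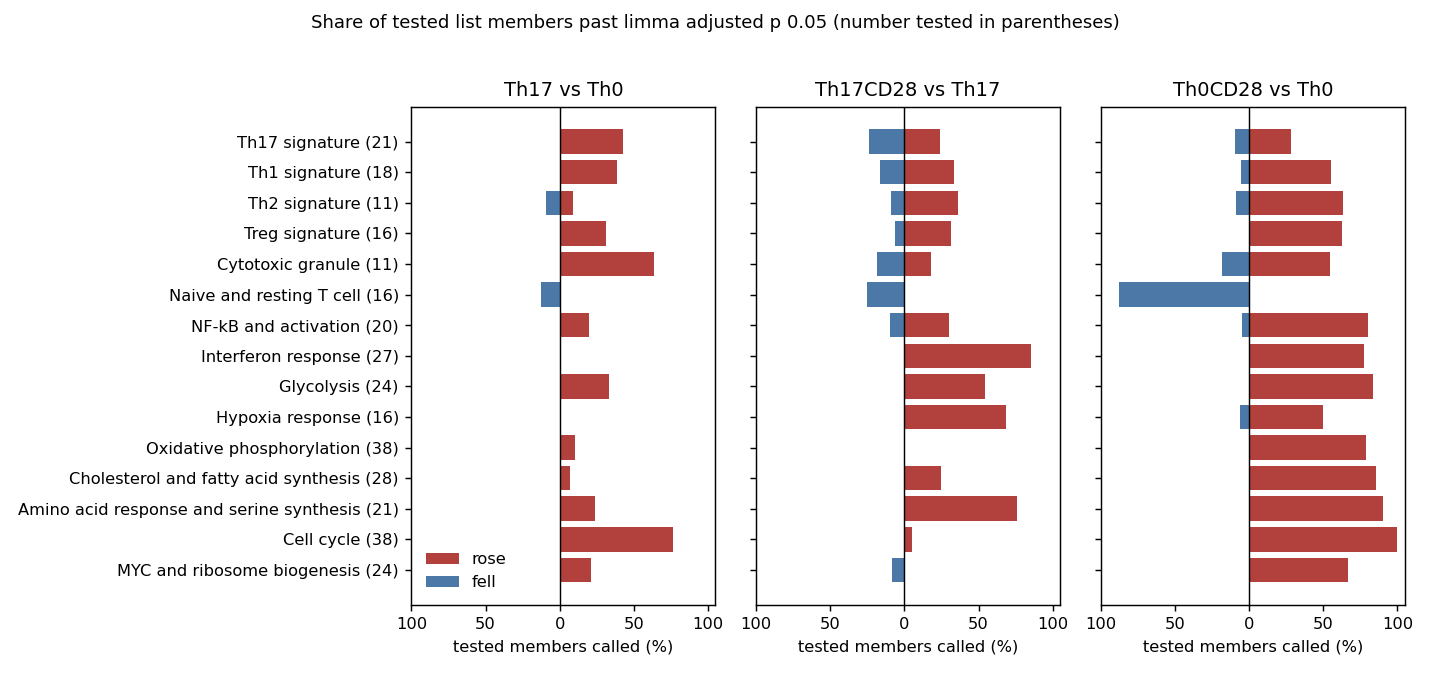
Share of tested members of 15 gene lists, in percent on the horizontal axis, that rose (to the right of 0) or fell (to the left) past the limma threshold in 3 comparisons, with the number tested in parentheses. In Th17CD28 against Th17, 23 of 27 interferon response genes rose, and in Th0CD28 against Th0 all 38 cell cycle genes rose.

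The comparison of Th0CD28 with Th0 gives the effect of anti-CD28 without the cytokines. All 38 tested cell cycle genes rose, and 38 did when adjusted over the list alone (camera adjusted p = 1.36e-16; adjusted p = 0.319 with an estimated correlation). UBE2C, a ubiquitin enzyme of mitosis, rose by 5.47 ± 0.50 (SE, n = 2 donors; limma adjusted p = 0.0011), TYMS by 5.37 ± 0.42, CDC20 by 5.34 ± 0.49 and MKI67 by 4.48 ± 0.40, the last from 1.13 ± 0.997 to 44.2 ± 5.90 FPKM (SD). The naive and resting list went the other way, with 14 of 16 members lower, also 14 when adjusted over the list alone (camera adjusted p = 9.66e-09; adjusted p = 0.26 with an estimated correlation): KLF2 fell by 4.84 ± 0.29, IL7R fell by 3.97 ± 0.33 and PIK3IP1 fell by 3.93 ± 0.24.

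Metabolic lists rose widely. The cholesterol and fatty acid list had 24 of 28 members higher (camera adjusted p = 4.69e-08, or 0.26 with an estimated correlation). Adjusted over the list alone, 24 were higher and 1 lower. SCD rose by 5.94 ± 0.30 and FADS2 by 5.83 ± 0.26. The glycolysis list had 20 of 24 members higher, 22 when adjusted over the list alone, with LDHA at 4.25 ± 0.36 and GAPDH at 3.62 ± 0.31 (camera adjusted p = 4.69e-08; adjusted p = 0.26 with an estimated correlation). The amino acid list had 19 of 21 members higher, 19 when adjusted over the list alone, with DDIT4 at 4.43 ± 0.26 and PHGDH at 3.75 ± 0.35 (camera adjusted p = 4.69e-08; adjusted p = 0.26 with an estimated correlation). In the oxidative phosphorylation list 30 of 38 members rose, 33 when adjusted over the list alone, such as CYCS at 2.61 ± 0.37 and UQCRQ, a subunit of respiratory complex III, at 2.42 ± 0.27 (camera adjusted p = 9.63e-08; adjusted p = 0.347 with an estimated correlation). Of 27 interferon response genes 21 rose, 23 when adjusted over the list alone, with IFI44L at 4.20 ± 0.49 and OAS3 at 3.83 ± 0.38 (camera adjusted p = 3.98e-07; adjusted p = 0.347 with an estimated correlation). This list call too was lost among genes with every coding transcript listed.

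Activation and effector genes rose too. Of 20 NF-kB and activation genes 16 rose and 1 fell, 17 and 2 when adjusted over the list alone, with LTA (lymphotoxin) at 3.74 ± 0.47 (camera adjusted p = 0.000197; adjusted p = 0.26 with an estimated correlation). Of 16 regulatory T cell list members 10 rose, 10 when adjusted over the list alone, with TNFRSF4 (OX40) at 5.11 ± 0.73 and IL2RA at 4.07 ± 0.26 (camera adjusted p = 0.000176; adjusted p = 0.319 with an estimated correlation). Of 18 Th1 list members 10 rose and 1 fell, 13 and 1 when adjusted over the list alone, with the chemokine receptor CXCR3 at 4.50 ± 0.47 (camera adjusted p = 0.000449; adjusted p = 0.26 with an estimated correlation). In the stress list 6 of 12 members rose and 1 fell, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.0378; adjusted p = 0.319 with an estimated correlation), a call lost with a filter at 5 FPKM and without Th0 replicate 1. CCR4 rose by 4.56 ± 0.47, IL13 by 4.62 ± 0.74, CSF2 (GM-CSF) by 4.80 ± 0.60, CST7 by 5.48 ± 0.39 and the inhibitory receptor PDCD1 by 3.81 ± 0.36. Of the 11 cytotoxic granule genes, CST7 among them, 6 rose and 2 fell, also 6 and 2 when adjusted over the list alone. This list did not pass (camera adjusted p = 0.206), and GZMB averaged 17.2 FPKM in Th0 and 12.3 in Th0CD28. Of the 21 Th17 list members 6 rose and 2 fell, also 6 and 2 when adjusted over the list alone (camera adjusted p = 0.6). RORA fell by 2.04 ± 0.28. IL17F differed by 0.07 ± 0.98 (adjusted p = 0.967) and averaged at most 0.119 FPKM in these conditions. Outside the lists, LGALS1 rose by 6.33 ± 0.78, the transcription factor BHLHE40 by 6.09 ± 0.34 and LIF by 6.06 ± 0.34, while NOG, a BMP antagonist, fell by 5.25 ± 0.34 and TRIB2 fell by 4.92 ± 0.23. The markers CD8B (3.08 ± 0.35), CD79A (2.00 ± 0.40) and CD68 (1.67 ± 0.41) rose with them, as did CD8A, from 0.18 to 2.42 FPKM. Other markers fell, among them FCER1G by -2.02 ± 0.24, KLRK1 by -1.28 ± 0.24 and TRDC by -0.86 ± 0.24, and the CD8 T cell list had 2 members higher and 2 lower.

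In all, limma with the donor as a term called 4837 of 12373 genes, 3140 higher and 1697 lower in Th0CD28, and all 4837 had the same sign in both donors. Again a call nearly requires this, and 82.85% of all tested genes had the same sign. The share of higher genes was 64.9%, and 45.7% with upper-quartile scaling or 47.1% with quantile normalization, which moved the median of all genes from 0.21 to -0.07 and -0.04. The CD68 call was lost without Th0 replicate 1, and the CD68, CD79A, CD8A and TRDC calls with no filter on low values. TRDC was also lost without Th0 replicate 1, Th0 replicate 2 or Th17 replicate 3. The effects of anti-CD28 with and without the cytokines share no library, but both come from 1 fit with shared variance estimates. Counts expected of independent lists are thus only a rough baseline. Of the genes called, 559 rose in both (187 by independent lists) and 249 fell in both (49.5). Another 1 rose with and fell without the cytokines (101), and 11 fell with and rose without them (91.6).

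The comparison of Th17CD28 with Th0CD28 gives the effect of IL-23 and IL-1β beside anti-CD28. IL17F averaged 91.5 ± 116 FPKM in Th17CD28 and 0.119 ± 0.0971 FPKM in Th0CD28 (SD, n = 2 donors), a difference of 5.24 ± 0.98 (SE; limma adjusted p = 0.406). IL22 differed by 2.88 ± 0.30 (adjusted p = 0.136), IL21 by 2.19 ± 0.25 (adjusted p = 0.136), IL26 by 2.78 ± 0.38 (adjusted p = 0.186), GZMB by 4.42 ± 0.56 (adjusted p = 0.147) and IFNG by 2.71 ± 0.47 (adjusted p = 0.403), each higher in Th17CD28 in both donors. The 4 libraries of Th0CD28 held IL22 at 4.05, 0.0097, 0.00169 and 2.72 FPKM, so repeats of 1 donor disagreed.

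No gene passed limma with the donor as a term over all genes (0 of 12373; lowest adjusted p = 0.136), where 1153 had an unadjusted p below the threshold and 619 are expected by chance. The limma fit on 13 libraries called 1993, a count that treats repeats as separate donors. With no filter on low values 7 genes were called, without Th0CD28 replicate 1 there were 2, IL22 among them, and without Th0 replicate 1, Th0 replicate 2 or Th0CD28 replicate 4 there was 1. Adjusted over the list alone, 4 of 21 Th17 list members passed, all higher: IL17F, IL22, IL26 and IL21 (camera adjusted p = 5.29e-07; adjusted p = 0.189 with an estimated correlation). In the cytotoxic list 3 of 11 passed when adjusted over the list alone, GZMB among them (camera adjusted p = 0.00545; adjusted p = 0.383 with an estimated correlation). With no filter on low values the list did not pass. Adjusted in the same way, 12 of 27 interferon response genes were higher and 1 lower, with a median of 0.92 (camera adjusted p = 6.21e-13; adjusted p = 0.383 with an estimated correlation). The hypoxia list had a median of 0.71 (camera adjusted p = 7.67e-09; adjusted p = 0.383 with an estimated correlation), the oxidative phosphorylation list -0.44 (camera adjusted p = 1.94e-07; adjusted p = 0.405 with an estimated correlation) and the MYC and ribosome biogenesis list -0.55 (camera adjusted p = 5.29e-07; adjusted p = 0.405 with an estimated correlation).

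The interaction compares the anti-CD28 effect with the cytokines to that without them. It was negative in all 38 cell cycle genes, with 21 called, 37 when adjusted over the list alone and a median of -3.05 (camera adjusted p = 2.11e-21; adjusted p = 0.401 with an estimated correlation). CDC20 went from 2.63 to 126 FPKM with anti-CD28 alone and from 61.4 to 80.8 FPKM beside the cytokines, an interaction of -4.73 ± 0.69 (SE, n = 2 donors; limma adjusted p = 0.043); UBE2C had -4.54 ± 0.71 and TYMS -4.49 ± 0.60. UHRF1, which maintains DNA methylation, had -4.93 ± 0.72, the centromere protein CENPM -4.75 ± 0.83 and the importin IPO4 -4.75 ± 0.51. The donors differed beside the cytokines. With anti-CD28, CDC20 fell in donor 1, from 98.4 and 89.3 to 92.0 and 72.3 FPKM. In donor 2 it rose from 29.1 to 82.2 and 76.8 FPKM. CENPM and UHRF1 also fell in donor 1 and rose in donor 2. In the MYC and ribosome biogenesis list 5 of 24 were called lower, 12 when adjusted over the list alone, with TFRC at -3.62 ± 0.50, SRM at -3.24 ± 0.33 and NOP16 at -2.21 ± 0.34 (camera adjusted p = 6.08e-07; adjusted p = 0.411 with an estimated correlation).

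Part of the effector genes did so too. Of 18 Th1 genes 4 were called lower and 14 did not pass, 7 when adjusted over the list alone, with CCL4 at -4.93 ± 0.56, CCL3 at -4.08 ± 0.62 and FASLG at -2.80 ± 0.33 (camera adjusted p = 0.000299; adjusted p = 0.317 with an estimated correlation). In the cytotoxic list 3 of 11 were called lower and 8 did not pass, 5 when adjusted over the list alone, with NKG7 at -4.41 ± 0.61 and CST7 at -3.23 ± 0.55 (camera adjusted p = 0.0106; adjusted p = 0.401 with an estimated correlation). Without Th0 replicate 2 or Th17 replicate 3 the list did not pass. IFNG (0.10 ± 0.67; adjusted p = 0.938) and GZMB (-0.10 ± 0.79; adjusted p = 0.952) showed no called interaction. IL2RA had -2.33 ± 0.37, and the receptor CXCR6 had -2.49 ± 0.39. Among metabolic genes SLC7A5 had -3.69 ± 0.48, the glycolytic enzymes PKM, ENO1 and PGAM1 -2.29 ± 0.40, -2.15 ± 0.38 and -2.08 ± 0.37, the desaturase SCD -2.32 ± 0.42, and the respiratory genes CYC1 and ATP5J -2.25 ± 0.37 and -2.23 ± 0.32. The Th17CD28 repeats of ATP5J disagreed, at 164 and 37.5 FPKM in donor 1 and 103.9 and 43.9 FPKM in donor 2. Called as lower were 3 of 24 glycolysis and 2 of 38 oxidative phosphorylation genes, 8 and 19 when adjusted over the list alone. So were 2 of 28 cholesterol and fatty acid and 1 of 21 amino acid genes. Over these lists alone 7 and 4 were lower, and 1 amino acid gene was higher. The first 3 lists passed (camera adjusted p = 0.00767, 6.81e-10 and 6.01e-05, or 0.42, 0.401 and 0.401 with an estimated correlation). The amino acid list did not (camera adjusted p = 0.0871). Some lists had a positive interaction. In the naive and resting list 1 of 16 members had a called positive one, 5 when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 3.08e-05, or 0.317 with an estimated correlation). This list fell with anti-CD28 in both settings, with medians of -1.33 without and -0.60 with the cytokines. Its positive interaction is thus a smaller fall. In the interferon response list 0 of 27 were called, 0 when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 0.000142; adjusted p = 0.453 with an estimated correlation). The hypoxia list had 0 of 16 called, 1 when adjusted over the list alone, and a median of 0.80 (camera adjusted p = 0.00107; adjusted p = 0.453 with an estimated correlation). Genes with a positive interaction included TPM2 at 2.34 ± 0.29, the kinase TXK at 2.33 ± 0.37, IL22 at 2.30 ± 0.42 (adjusted p = 0.0489), FAM153A at 2.21 ± 0.34 and GIMAP7 at 2.09 ± 0.38. TPM2 and GIMAP7 also fell with anti-CD28 in both settings. GIMAP7 went from 362 to 29.6 FPKM without the cytokines and from 148 to 52.1 FPKM with them. IL17A (adjusted p = 0.147) and IL17F (-3.48 ± 1.38; adjusted p = 0.19) did not pass.

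In all, limma with the donor as a term called 280 interactions, 25 positive and 255 negative. Upper-quartile scaling and quantile normalization moved the median of all genes from -0.04 to 0.12 and 0.11 and gave 153 and 96 calls. Of the 28 genes named here as called, upper-quartile scaling lost 12 (CCL3, CENPM, CST7, CXCR6, CYC1, ENO1, IL22, IL2RA, PGAM1, PKM, SCD and UBE2C). Quantile normalization lost 15, the same ones without CXCR6 and with ATP5J, CDC20, FAM153A and GIMAP7. The count was 7 with no replicate block and 12 with no filter on low values, and each of these lost all 28 genes named here as called. It was 480 with a filter at 5 FPKM (CXCR6 and IL22 lost), 441 with a pseudocount of 0.1 (CENPM, CST7, CXCR6 and IL22 lost), and 12 without Th17CD28 replicate 4, which lost all 28 too. It was 18 without Th17CD28 replicate 1 and 33 without Th0 replicate 2, and in both cases only CCL4, IPO4 and SRM kept their calls among the 28. It was 124 without Th17 replicate 3, 150 without Th17 replicate 1, 156 without Th0CD28 replicate 3, 181 without Th0CD28 replicate 1 and 429 without Th17CD28 replicate 2. Without Th17 replicate 3, 18 of the 28 missed the threshold (ATP5J, CCL3, CENPM, CST7, CXCR6, CYC1, ENO1, FAM153A, GIMAP7, IL22, IL2RA, NKG7, NOP16, PGAM1, PKM, TPM2, TXK and UBE2C). ENO1, GIMAP7, PGAM1, PKM and SCD missed it without Th0 replicate 1, Th17 replicate 1, or Th0CD28 replicate 1, replicate 3 or replicate 4. CENPM did without the same libraries except Th0 replicate 1, and CST7 without them except Th0CD28 replicate 4. NOP16 was also lost without Th0 replicate 1, CCL3 without Th17 replicate 1, SCD without Th17 replicate 2 and ATP5J without Th17CD28 replicate 2. The IL22 interaction, whose Th0CD28 repeats disagreed, kept its call only without Th0CD28 replicate 1, Th17CD28 replicate 2 or Th17CD28 replicate 3 among the libraries. It was also lost with mitochondrial transcripts left out.

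**Figure D3:**
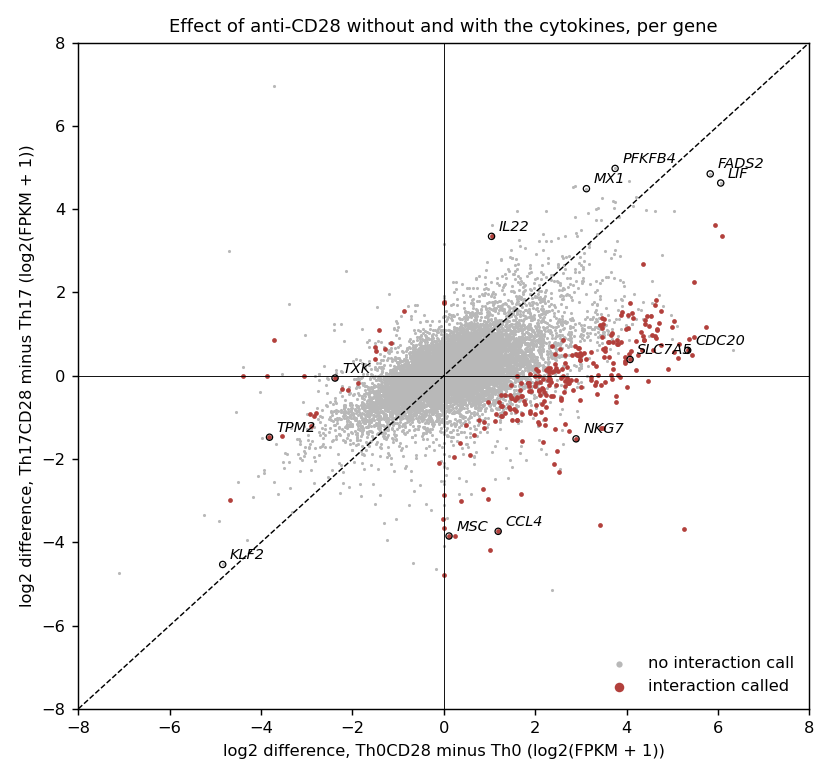
Effect of anti-CD28 per gene without the cytokines (horizontal axis, Th0CD28 minus Th0) and with them (vertical axis, Th17CD28 minus Th17), both as log2 differences of FPKM + 1; red points are the 280 genes with a called interaction, gray points the rest, and the dashed line marks equal effects. Of the red points 255 lie below the line and 25 above it.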

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

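The monocyte test, the test of scaling for the comparison without calls and the settings with every coding transcript listed were chosen only after the results were seen. Of 212 sets of 4 libraries checked for a library far from the other 3, 2 stood out. Chance would give about 11 if the 4 values were independent, but each set held 2 repeats of each donor. A library beside its own repeat can hardly stand out, so the low count says little about the libraries. KRT72 in Th17CD28 had 1 library at 0.498 FPKM against 0.343 to 0.354 (gap over range 0.927), and MX1 in Th17CD28 had 1 at 379 FPKM against 325 to 332 (0.871).

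The anti-CD28 effect differed between cells with and without the cytokines in 280 genes. Beside the interactions of CDC20 (-4.73), UBE2C (-4.54), TYMS (-4.49), UHRF1 (-4.93), CENPM (-4.75), IPO4 (-4.75), TFRC (-3.62), SRM (-3.24), RRP9 (-1.85) and NOP16 (-2.21) stood MKI67 (-3.28), RRM2 (-4.46) and BHLHE40 (-2.74). Effector and surface genes were CCL4 (-4.93), CCL3 (-4.08), NKG7 (-4.41), CST7 (-3.23), FASLG (-2.80), IL2RA (-2.33), CXCR6 (-2.49), and TNFRSF8 (-3.76). The enzyme gene FUT7 had -4.09 and the transcription factor gene MSC -3.96. Metabolic genes were SLC7A5 (-3.69), PKM (-2.29), ENO1 (-2.15), PGAM1 (-2.08), SCD (-2.32), CYC1 (-2.25) and ATP5J (-2.23). Of the 7 interactions given only here (MKI67, RRM2, BHLHE40, RRP9, TNFRSF8, FUT7 and MSC), all 7 calls were lost with no replicate block, with no filter on low values and without Th17CD28 replicate 1 or Th17CD28 replicate 4, and 6 (all but MSC) without Th0 replicate 2. Without Th17 replicate 1, BHLHE40, MKI67, RRP9 and TNFRSF8 were lost. BHLHE40, MKI67 and RRP9 were lost with either other scaling and without Th0CD28 replicate 3 or Th17 replicate 3. RRP9 was lost without Th0CD28 replicate 4, RRP9 and TNFRSF8 without Th0 replicate 1, and both with BHLHE40 without Th0CD28 replicate 1. BHLHE40 was also lost with a pseudocount of 0.1 and with mitochondrial transcripts left out. Positive were TPM2 (2.34), TXK (2.33), IL22 (2.30), FAM153A (2.21) and GIMAP7 (2.09).

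Interferon response genes were higher with anti-CD28 beside the cytokines, with a median of 3.24 over 27 tested members. The tables argue against scaling of the libraries as the cause, since the lower of the medians under upper-quartile scaling and quantile normalization was 3.09. Monocyte RNA in the libraries is argued against too as the source of the rise. The 6 abundant monocyte genes LYZ, S100A8, S100A9, CD14, FCN1 and VCAN summed to 0.345 FPKM in Th17CD28 and 0.603 in Th17. All 13 members of the monocyte list together rose by 1.08 and 2.66 FPKM in the donors. The summed interferon genes rose by 2723 and 3807 there. Among the 13, CD68 rose by 3.11 and FCER1G fell by 1.37 on the log2 scale. Whether monocytes, present or lost during the culture, acted on the T cells cannot be told from these values. Transcripts missing from the table stay open for the size of the rise: the 7 members with every coding transcript listed had a median of 1.94 with a standard error of 0.533. That error treats genes as independent, whereas the list had an estimated correlation of 0.60. All 7 rose, by 1.11 to 4.01, and 5 were called. These 7 were picked for having no coding transcript missing, so they decide nothing on missing transcripts in the other members. A response to interferon made in cultures with anti-CD28 may be the cause and was not tested.

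For the cytokines with anti-CD28 no gene was called across donors, while 1993 were called when repeats counted as separate observations. A test in 10862 genes gave a residual variance of the donor means 7.02 times that expected from independent libraries with the spread of the repeats. This decides nothing on whether repeat libraries of a donor vary less than donors do, because the labels do not say if the repeats were separate cultures, and technical ones alone would give a ratio above 1. Scaling of the libraries is argued against, since upper-quartile scaling and quantile normalization gave at most 0 calls. A difference between the donors in their response to the cytokines, or between their cultures, was not tested and stays open.

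The anti-CD28 effect on cell cycle genes was smaller with the cytokines, with a median interaction of -3.05 over 38 genes. Scaling of the libraries is argued against as the whole cause, since the median closer to 0 under either scaling was -2.86. A single library is argued against for the size, since the median closest to 0 with 1 library left out was -2.93 (without Th0 replicate 2), but the number of members called fell as low as 0. Cell cycle genes were already higher in Th17 than in Th0, so a ceiling of proliferation may contribute, as a hypothesis that was not tested.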

How the results depend on the processing

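The settings with transcripts as features, every coding transcript listed, mitochondrial transcripts left out, and a camera correlation estimated on 13 libraries were chosen only after the results were seen. Counts are given in the order Th17CD28 against Th17 (1098), Th17 against Th0 (612), Th17CD28 against Th0CD28 (0), Th0CD28 against Th0 (4837) and interaction (280), and only where they moved by over 1.5 times. With no filter on low values, which adds genes near 0 to the 12373 tested, the first 3 were 111, 22 and 7 and the interaction 12. With no replicate block the paired comparisons gave 713 and 294 and the interaction 7; the block moved no other count by over 1.5 times, and without it 48 of the 152 calls of named genes and 5 of the 75 gene list calls were lost. With 13 libraries as observations all but Th0CD28 against Th0 moved, to 5035, 3555, 1993 and 4339 for the interaction. With every coding transcript listed, where fewer genes were tested, the first 2 were 458 and 308, and Th0CD28 against Th0 1355. The interaction also moved to 441 with a pseudocount of 0.1, 480 with a filter at 5 FPKM, 153 with upper-quartile scaling, 96 with quantile normalization and 20 with transcripts as features. The cause was not tested except where it lies in the number of genes or samples.

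Leaving out each library in turn gave 54 to 1615, 336 to 842, 0 to 2, 3243 to 5297 and 12 to 429 calls; where this left a condition with 1 donor, that donor was assumed to vary like the rest. Of the list calls 0 of 75 held with an estimated correlation and 8 with one estimated on 13 libraries. The Th1 list in Th17 against Th0 also lost its call, at a correlation of -0.0098, under the preset 0.01 (camera adjusted p = 0.0959). The 3 residual degrees of freedom thus enter these losses, and the correlation alone does not explain them. Among lists called in the main fit or in the other setting, directions turned in 3 cases. Turns of lists called in neither were not counted. The chemokine and homing receptor list in Th17CD28 against Th17 had a median of 0.57 among genes with every coding transcript listed. In Th17 against Th0 the interferon list ranged from -0.12 (without Th17 replicate 3) to 0.39 (without Th0 replicate 1). The mitochondrial list there ranged from -0.39 (without Th0 replicate 2) to 0.71 (without Th0 replicate 1). The read depth is unknown, so which low values it limits cannot be given; 491 of 12373 genes had 1 repeat under 0.01 FPKM beside another of at least 1 FPKM.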

Other observations

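The tests of library splits were chosen only after the results were seen. The 2 genes named next were picked once their values were known. Genes called in opposite directions by anti-CD28 with and without the cytokines were few, 12 in all. SRM, which makes spermidine, fell by 1.03 with the cytokines and rose by 2.21 without them, and RRP9, a factor of ribosomal RNA processing, fell by 1.06 and rose by 0.78. Anti-CD28 effects with and without the cytokines correlated across genes at r = 0.555; genes are not independent replicates, and both effects come from 1 fit with shared variance estimates.

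A hypothesis was that a group of genes is high only with the cytokines and without anti-CD28. Of 77 genes at least 4-fold higher in Th17 than in both Th0 and Th17CD28 in donor 1, 64.9% were higher in both comparisons in donor 2, against 16.9% of genes matched on expression. Of 62 genes defined in donor 2, 48.4% were higher in donor 1, against 21.5%. The shares lie above those of matched genes but below the 80% set for a shared group, so the test left the hypothesis open. Of the 21 genes defined in both donors 9 are annotated as protein-coding, among them IL17F, MSC, FUT7 and TUBB3. This count leaves out genes without a listed transcript in the annotation, such as the chemokine gene CCL4, which is also among the 21. The donor 2 set was picked from 1 library each of Th0 and Th17. As a hypothesis that was not tested, anti-CD28 may end a programme that the cytokines alone sustain. The shares of 64.9% and 48.4% do not tell a programme that ended from one that did not start.

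The 7 libraries of Th17CD28 and Th17 were split into groups of the same sizes in 35 ways, and each split was fitted on single libraries, with the donor as a term except where the split was the donors themselves. The real split called 5343 genes (1 of 35 reached this), and the highest other, which parted the donors and had no donor term, called 46. For the 8 libraries of Th17CD28 and Th0CD28 the real split called 2863 genes (1 of 35), and the highest other, again that of the donors, 535. Repeats of 1 donor are not separate donors, so only splits that keep repeats together compare with the real one, and the 3 of these in each case are too few for a share under 0.05.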
